A study of Homo sapiens with 2 samples.

How the data were processed

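RNA was measured in 2 samples of the human line G401, 1 labelled with a control guide and 1 with a guide against HOXB13, and both groups were taken from the sample titles. Per the labels, the cells were harvested when subconfluent, total RNA was extracted with an RNeasy kit, ribosomal RNA was removed with a RiboMinus kit, and libraries were prepared with an Ion PI template kit. Per the submitters' processing notes, Bowtie, TopHat and Cufflinks were used with the build hg19, and versions, settings and the strand mode were not given in the sources used here. Without strand, reads from a gene and an overlapping antisense gene cannot be told apart. In the tables HOXB13 and its antisense neighbour HOXB-AS5, which ends at 46802119, do not overlap.

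The authors deposited 1 table of FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per library, each with 25001 rows that hold a gene symbol and an hg19 locus, and no read counts or confidence limits. FPKM values written as 0.001 in the deposited tables stood for 0, with nothing below them, and applied to 8206 rows of the control library and 8301 of the HOXB13-guide library. Estimates marked as failed were kept out of all results: among them RPL11 and SLC7A2 failed in the HOXB13-guide library and SERBP1 in the control. A spreadsheet had turned 26 symbols into dates, and the 17 of these that were tested were counted but not named. The 482 symbols on several rows (2027 rows in all) were summed, which left 23456 symbols, 23452 of them with a value. The FPKM of all rows summed to 518169 in the control library and 524277 in the HOXB13-guide library, the 100 highest rows held 34.5% and 35.2% of it, and ribosomal proteins 26.3% and 25.9%. Coordinates are given from 1, as start positions in the tables counted from 0.

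The design fixed before the data were examined named no test, because each group had 1 library. A gene was tested at FPKM of at least 1 in either library, which left 11970 genes, and its ratio was log2 of (FPKM + 1) in the HOXB13-guide library over (FPKM + 1) in the control, with the deposited values unscaled. A gene counted as higher or lower at 2-fold or more, which is a rule of size and not of significance. Genes were named by a fixed rule. It took HOXB13, then the 12 highest and 12 lowest ratios among genes with FPKM of at least 5 in the higher library and above 0 in both, without short RNA and uncharacterised locus symbols. Up to 5 genes in each direction listed at 0 in 1 library and at 5 FPKM or more in the other would have followed, and none qualified, since the 8 such symbols were short RNAs, whose FPKM is unsteady. Then came up to 4 members of each list with the largest absolute ratio. Genes outside the rule are said to be so where they appear, apart from HOXB-AS5, PRAC and SMARCB1, which were added after the data were seen as the neighbours of HOXB13 and as a marker of rhabdoid cells. Some genes that the rule named are not reported here.

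The 33 gene lists were also fixed before the data were examined and covered HOX genes and cofactors, chromatin complexes, cell cycle, metabolism, stress, signalling targets, lineage markers of kidney, nerve, muscle, endothelium and leukocytes, short RNAs and housekeeping genes. A list with at least 5 tested members was set against 10000 random lists of the same size, drawn from the other tested genes and matched on mean expression in 20 bins. It stood apart when its median lay at or below percentile 2.5 or at or above percentile 97.5 of the random medians. These percentiles describe the 2 libraries and are not p-values. Chromosomes were treated in the same way. HOXB13 was also compared with the 200 genes nearest in mean level. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

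Depth was estimated from the FPKM values of 2396 genes below 0.3 FPKM in both libraries. Ratios between the libraries matched ratios of whole numbers up to 12 within 0.0002 for 57.1% of these genes, and for 0.835% after a random shift, and 305 genes shared the ratio 1.02, the value of 1 read in the HOXB13-guide library over that in the control. Among 118 single-exon genes, 54 gave 1 common depth when 196 nt were subtracted from the gene length, which put the libraries at 23.9 M and 23.4 M reads. The 196 nt were chosen because they gave the most genes in agreement, with no random comparison, and the other genes gave other depths. The locus width equalled the annotated length for 26 of the 118, so the depth is approximate. Reads were not recovered for all genes, so no count test was run. The interval of HOXB13 used a transcript length from GENCODE 29, a reference for another build used here for lengths only, and covers counting error only. The procedure was tested on simulated data for the 11751 genes of this comparison that entered it, with log2 noise of SD 0.45. It recovered 99 of 100 genes planted at 4-fold and 100 of 100 at 8-fold, and of lists of 25 members 6 of 100 unchanged ones and 99 of 100 shifted by 0.4 stood apart. Planted genes had at least 5 FPKM in the control, and recovery meant passing 2-fold in the planted direction. The noise was small beside the planted changes, so this recovery followed from the settings. It gives no rate of false calls among unchanged genes. The unchanged lists were random genes with independent noise, so their rate followed from the percentile limits. It need not hold for lists whose members vary together.

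Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM in either library or a mean FPKM of 1, and 4 scalings (median centring, upper quartile, equal total, and a trimmed mean of log ratios with 30% of ratios and 5% of levels trimmed). The highest row per symbol, lists without short RNAs, list means and unmatched random lists were tried too. Centring on the housekeeping list and leaving shared or extreme members out of 4 lists were added after the data were seen.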

Results

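The transcriptome of G401 cells, a human cell line from a rhabdoid tumor of the kidney, was measured by RNA sequencing after CRISPR targeting of HOXB13. HOXB13 is a homeobox transcription factor of the posterior HOXB cluster. The data held 2 libraries, 1 from cells that carried a control guide and 1 from cells that carried a guide against HOXB13, and the comparison asked what targeting this gene did to gene expression. Each group had 1 library, so no difference below had a replicate check and no p-value was computed. Values were FPKM per gene, of which 11598 genes reached 1 or more in the control library and 11528 in the HOXB13-guide library. The depth, estimated from the steps between low FPKM values, was about 23.9 M reads in the control library and 23.4 M in the HOXB13-guide library. Among 11970 genes with FPKM of at least 1 in either library, the ratio of HOXB13-guide over control FPKM was taken on the log2(FPKM + 1) scale, which understates the ratio of low genes.

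HOXB13 mRNA was lower in the library that carried its guide. The gene lies on chromosome 17 from 46802127 to 46806111 in hg19, and its level was 14.6 FPKM in the control library and 4.50 FPKM in the HOXB13-guide library, a log2 ratio of −1.50, or 2.83-fold lower with the pseudocount and 3.24-fold lower without it. The adjacent genes did not share this direction: HOXB-AS5 had 3.34 FPKM in the control and 5.76 in the HOXB13-guide library, and PRAC had 0.920 and 1.41. The remaining HOXB genes with PRAC gave 7 tested members, none of them past 2-fold, with a median log2 ratio of 0.30. HOXB6 (0.367 and 1.01 FPKM) and PRAC reached 1 FPKM in the HOXB13-guide library only. HOXB3, named outside the rule, did so in the control only (1.16 and 0.846). Among these, HOXB7 had 3.33 and 6.06 FPKM, whereas HOXB2 had 6.96 and 5.07. With the estimated depths and a transcript of 3467 nt, the HOXB13 values stood for about 1139 and 344 reads, and the HOXB13-guide library held 30.9% of the control level (exact 95% interval 27.3 to 34.8%, counting error only). Of the 200 genes nearest to HOXB13 in mean level, 5 had a ratio as low or lower, which is 2.5% of them. The guide's target position was not given in the sources used here, and small insertions or deletions in a coding sequence need not lower the mRNA, so its level did not measure editing.

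Of the genes named by the rule of size, WLS had the highest ratio in the HOXB13-guide library. WLS, which carries WNT ligands to the cell surface, had 2.12 FPKM in the control and 275 in the HOXB13-guide library (log2 6.47). COL11A1, a fibrillar collagen chain, had 1.94 and 167 FPKM (log2 5.83), and SOST, a secreted WNT antagonist, had 3.43 and 102 (log2 4.54). TPM1, a tropomyosin that lies along actin filaments, was abundant in both libraries, at 38.9 and 674 FPKM (log2 4.08). Of the insulin-like growth factor binding protein IGFBP3 the control library held 0.0863 FPKM and the HOXB13-guide library 51.3 (log2 5.59). RND3, an atypical small GTPase, had 1.90 and 89.2 FPKM, and the transmembrane protein gene TMEM178A had 1.67 and 69.6. The heparan sulfate proteoglycan SDC2 had 0.0254 and 15.0 FPKM, and SULF1, an enzyme that trims sulfate from heparan sulfate, had 0.125 and 17.4. The secreted guidance factor SEMA3C had 0.00837 and 24.9 FPKM, the membrane glycoprotein gene PROM1 0.0114 and 17.6, and the LIM-domain gene FHL1 0.414 and 21.0.

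The genes with the lowest ratios were led by CPE, which processes peptide hormones, with 111 FPKM in the control and 1.57 in the HOXB13-guide library (log2 −5.45). Members of the stress list followed among the lowest: TRIB3, a pseudokinase, had 161 and 5.57 FPKM (log2 −4.62), CHAC1, which degrades glutathione, had 83.8 and 3.18 (log2 −4.34), and DDIT3, a stress transcription factor, had 142 and 9.25 (log2 −3.81). INHBE, an inhibin subunit gene, had 32.0 and 0.266 FPKM (log2 −4.70). CDH1, which encodes E-cadherin, had 32.3 and 1.28 FPKM (log2 −3.87), and TXNIP, an inhibitor of thioredoxin, had 20.1 and 0.624 (log2 −3.70). PRICKLE1, of the planar cell polarity pathway, had 21.9 and 0.189 FPKM, and the transglutaminase gene TGM1 had 17.4 and 0.165. CPED1, SPATS1 and KLHDC7B completed the group, with 25.4, 30.4 and 16.5 FPKM in the control and 0.457, 0.892 and 0.0152 in the HOXB13-guide library.

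**Figure D1:**
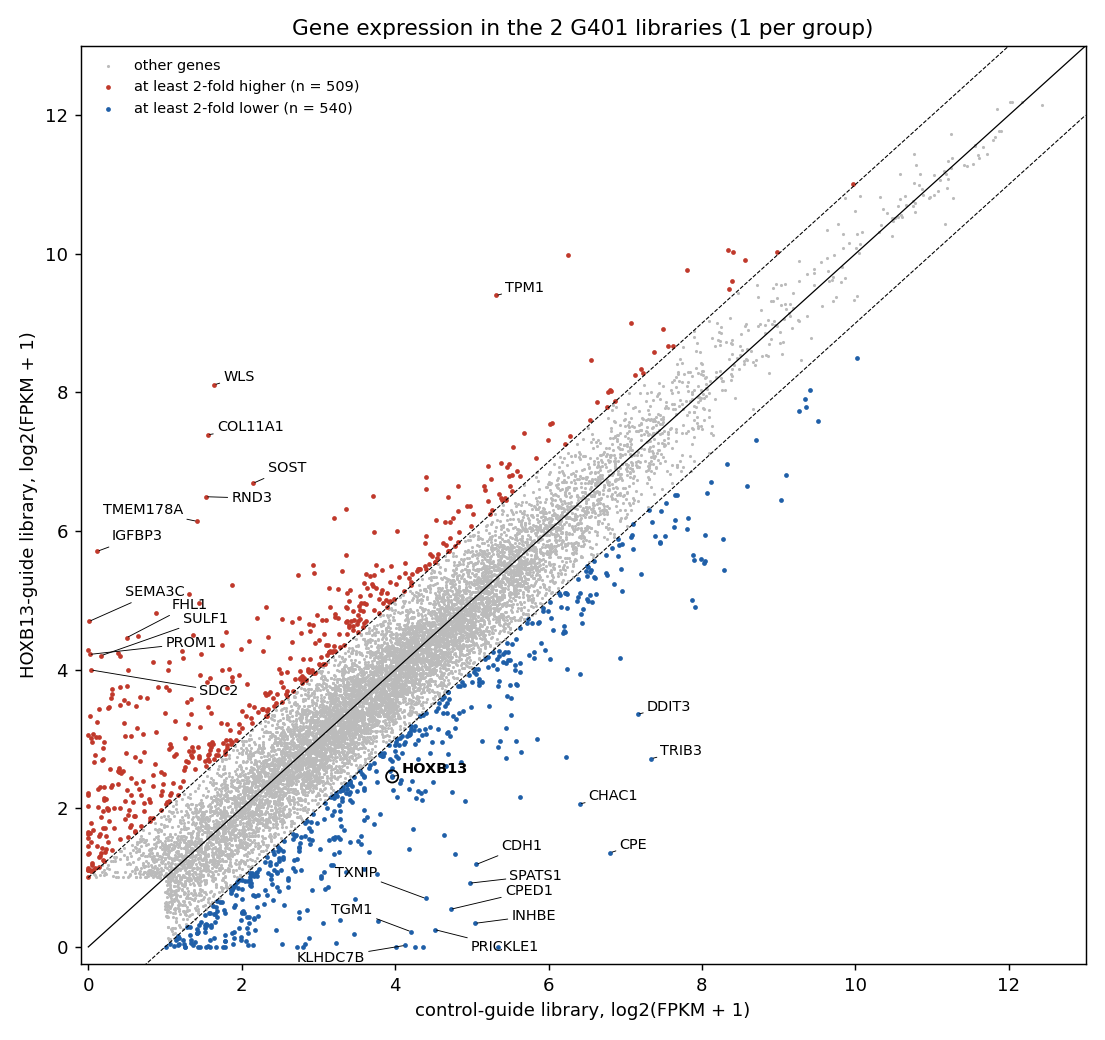
Expression of each tested gene in the control-guide library (horizontal) and the HOXB13-guide library (vertical), both as log2(FPKM + 1), with 1 point per gene and 1 library per axis. Dashed lines mark 2-fold, red points the 509 genes at least 2-fold higher and blue points the 540 at least 2-fold lower; HOXB13 is circled at 14.6 and 4.50 FPKM, and WLS and CPE lie farthest from the diagonal among the labelled genes.

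In all, 509 genes (4.25%) were at least 2-fold higher in the HOXB13-guide library and 540 (4.51%) at least 2-fold lower, and 118 and 84 passed 4-fold. The median log2 ratio was −0.05, with quartiles of −0.38 and 0.29, and the correlation of log2(FPKM + 1) between the libraries across 11156 genes at 1 FPKM or more in both was r = 0.943 (genes are not independent replicates). The share of genes past 2-fold was 12.7% at a mean FPKM of 1 to 2, 6.71% at 10 to 50 and 9.11% at 50 or more. Of the genes past 2-fold, 48.5% were higher with the values as deposited. The 4 planned scalings gave 46.5% (equal total), 52.2% (upper quartile), 54.5% (median centring) and 54.7% (trimmed mean). The share was 18.6% (287 higher, 1255 lower) when ratios were centred on the housekeeping list, a setting added after the data were seen. That list itself stood above its random range.

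Genes of the unfolded protein and integrated stress responses formed the list with the lowest median. Of 35 tested members, 22 were at least 2-fold lower and 4 at least 2-fold higher in the HOXB13-guide library, and the median log2 ratio of −1.40 lay below all 10000 random lists of like size and expression (percentile 0; central 95% from −0.20 to 0.18). The transcription factor gene ATF4 had 416 FPKM in the control and 158 in the HOXB13-guide library. ASNS, which makes asparagine, had 310 and 42.6 FPKM, PSAT1, of serine synthesis, had 524 and 86.3, and the secreted glycoprotein gene STC2 had 8.34 and 0.0413. The 4 higher members were residents of the endoplasmic reticulum: CALR had 134 and 513 FPKM, PDIA4 44.2 and 99.3, CRELD2 10.4 and 26.5, and SDF2L1 4.77 and 25.6. Members of that compartment went both ways, with 7 of 15 chaperone and degradation genes below 0. Of these HERPUD1, at 61.2 and 18.4 FPKM, and HYOU1, at 95.5 and 46.2, were at least 2-fold lower. ATF4, ASNS, PSAT1, HERPUD1, HYOU1 and the 4 higher members were named after their values were seen, apart from the rule that picked the other genes.

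DNA replication genes were higher as a list in the HOXB13-guide library, mitotic genes had a smaller median near that of housekeeping genes, and replication-dependent histones lay within the random range. Of 40 DNA replication and G1/S genes, 16 were at least 2-fold higher and none 2-fold lower, with a median log2 ratio of 0.89 (percentile 100). UHRF1, which maintains DNA methylation, had 9.65 FPKM in the control and 34.4 in the HOXB13-guide library, the ribonucleotide reductase genes RRM1 and RRM2 had 22.1 and 12.2 in the control against 70.2 and 40.2, and the helicase subunit MCM4 had 20.1 and 60.1. Of 51 mitosis and G2/M genes, 40 had ratios above 0 but 4 passed 2-fold, with a median of 0.37 (percentile 100). These were ANLN at 12.1 and 35.8 FPKM, MKI67 at 6.72 and 19.8, TUBB4B at 110 and 262 and CDC20 at 40.9 and 86.2. Of 57 replication-dependent histones on the list 24 were tested, with 1 higher, 3 lower and a median of −0.18, HIST1H1C having 8.25 and 27.0 FPKM and HIST1H2BN 5.59 and 1.40. These mRNAs, which mostly lack poly(A) tails, were near absent in part: HIST1H4C was listed at 0 in the control and had 0.226 FPKM in the HOXB13-guide library, and HIST1H3B had 0.154 and 0.473, both named after their values were seen. Not all were low. The highest were HIST1H2BK, at 121 and 70.6 FPKM, and HIST3H2A, at 38.7 and 25.6, also named after their values were seen. Of the 24 tested, 9 had ratios above 0 and 15 below. Why the near absent members were so low in libraries labelled as depleted of ribosomal RNA was not tested. With those members missing, the histone list cannot show whether histone mRNAs as a set followed the replication genes. The 26 housekeeping genes also lay above the random range, with a median of 0.31 (percentile 99.7), and the G2/M median stood close to it. The background set by the design was the matched random lists, whose upper limit was 0.11 for G2/M, and not the housekeeping genes. Of the housekeeping genes B2M had 197 and 405 FPKM, GAPDH 928 and 1790 and CHMP2A 85.6 and 48.4.

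Lists of metabolic genes also had medians above 0. Cholesterol and fatty acid synthesis genes had 28 of 29 tested members above 0, 8 of them at least 2-fold higher and none 2-fold lower, with a median of 0.78 (percentile 100). The desaturase FADS2 had 27.3 FPKM in the control and 99.3 in the HOXB13-guide library, the sterol sensor INSIG1 5.32 and 20.2, and the sterol reductase DHCR7 10.8 and 30.1. Nuclear genes of oxidative phosphorylation had 57 of 67 members above 0, 4 past 2-fold and a median of 0.32 (percentile 100). This was near the housekeeping median of 0.31, and both lists hold SDHA. The largest ratios of the oxidative phosphorylation list belonged to ATP5G1, at 43.1 and 120 FPKM, NDUFB8, at 92.3 and 193, NDUFA4, at 42.1 and 88.0, and COX6B1, at 107 and 220. The glycolysis and hypoxia list went both ways among its 32 tested members, with 4 at least 2-fold higher, 3 at least 2-fold lower and a median of 0.40 (percentile 99.99). The glycolytic enzymes PKM and PFKP had 339 and 26.0 FPKM in the control and 1046 and 71.6 in the HOXB13-guide library, whereas VEGFA, an angiogenic factor, had 46.5 and 6.83 and DDIT4, an inhibitor of mTOR signalling, had 545 and 112. Without the members shared with the housekeeping list (GAPDH, GPI and PGK1) the median of the other 29 was 0.25 (percentile 99.4). The housekeeping median of 0.31 still includes those shared members, so it is not a like comparison. Summarised by its mean of 0.12 the full glycolysis and hypoxia list lay within the random range. Heat shock genes had 14 of 16 members above 0, 4 of them past 2-fold, and a median of 0.50 (percentile 99.97). HSPA8 had 222 and 868 FPKM, and HSPE1 109 and 255, while HSPA1A and HSPA1B, with 7.04 and 10.7 FPKM in the control and 20.6 and 32.4 in the HOXB13-guide library, are near-identical copies whose reads are uncertain between them. The androgen response list, with 16 tested, 3 higher and none lower past 2-fold and a median of 0.40 (percentile 99.6), owed its place to genes it shared with the cholesterol list: without the shared members, INSIG1 and SCD among them, the median of the other 13 was 0.04, within the random range. Of its members outside the cholesterol list, SLC45A3 had 0.799 and 2.63 FPKM.

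Extracellular matrix genes were higher as a list, and the kidney lists lay within the random range in the main setting. Of 22 tested extracellular matrix and mesenchyme genes, 7 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.81 (percentile 100), and without COL11A1 and S100A4 the median was 0.62 (percentile 100). S100A4, a calcium-binding protein gene, had 75.6 FPKM in the control and 1009 in the HOXB13-guide library, COL3A1 had 40.6 and 126, and THBS1, which encodes thrombospondin, had 0.522 and 5.65. With no filter on low values the list's median was 0.02, within the random range. The epithelial and kidney tubule list had 9 tested members and a median of −0.16, within the random range, with CDH1 its only member past 2-fold, and KRT18 had 1023 and 1572 FPKM. Among 10 tested nephron progenitor and renal development genes, 3 were at least 2-fold lower and 1 at least 2-fold higher (median −0.41, percentile 3.66, within the range). This list stood below the random range with a pseudocount of 0.1 FPKM (median −0.60), by its mean of −0.52 and against random lists not matched on expression (median −0.41). The growth factor gene FGF8 had 39.7 and 6.35 FPKM, FOXD1 11.6 and 1.57, DLK1 3.51 and 0.184, and MEOX1 8.59 and 25.9. The 5 tested members of the skeletal muscle list had a median of 0.63 (percentile 98.7), with TNNT2, which encodes cardiac troponin T, at 1.57 and 21.6 FPKM. With no filter on low values the median was 0.07 and within the range. MYOD1, MYOG and DES, named outside the rule, were below the limit for testing in both libraries. The 6 tested neural genes had a median of 0.42 (percentile 96.9, within the range), with TUBB3 at 30.5 and 81.0 FPKM and ELAVL3 at 1.70 and 0.162.

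HOX genes outside the HOXB cluster were lower as a list. Of 21 tested HOXA, HOXC and HOXD genes 17 had ratios below 0 and 3 were at least 2-fold lower, with a median of −0.48 (percentile 0.11). The lowest ratio was that of HOXC11 (log2 −1.29), and HOXD8 had 6.37 FPKM in the control and 2.28 in the HOXB13-guide library, and HOXD3 had 1.73 and 0.243. The list of their cofactors of the MEIS, PBX and PREP (PKNOX) families also held TGIF1 and TGIF2, both tested, so its median is not that of the cofactors alone. It had 7 tested members, none past 2-fold, and a median of −0.19, within the random range, with MEIS2 at 71.6 and 37.3 FPKM. The polycomb list had 22 tested members, 1 lower and none higher past 2-fold, and a median of −0.06. The SWI/SNF list had 21 tested members, none past 2-fold, and a median of −0.20. SMARCB1, the subunit whose loss defines most rhabdoid tumors, was near absent from both libraries, at 0.113 and 0.0577 FPKM.

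**Figure D2:**
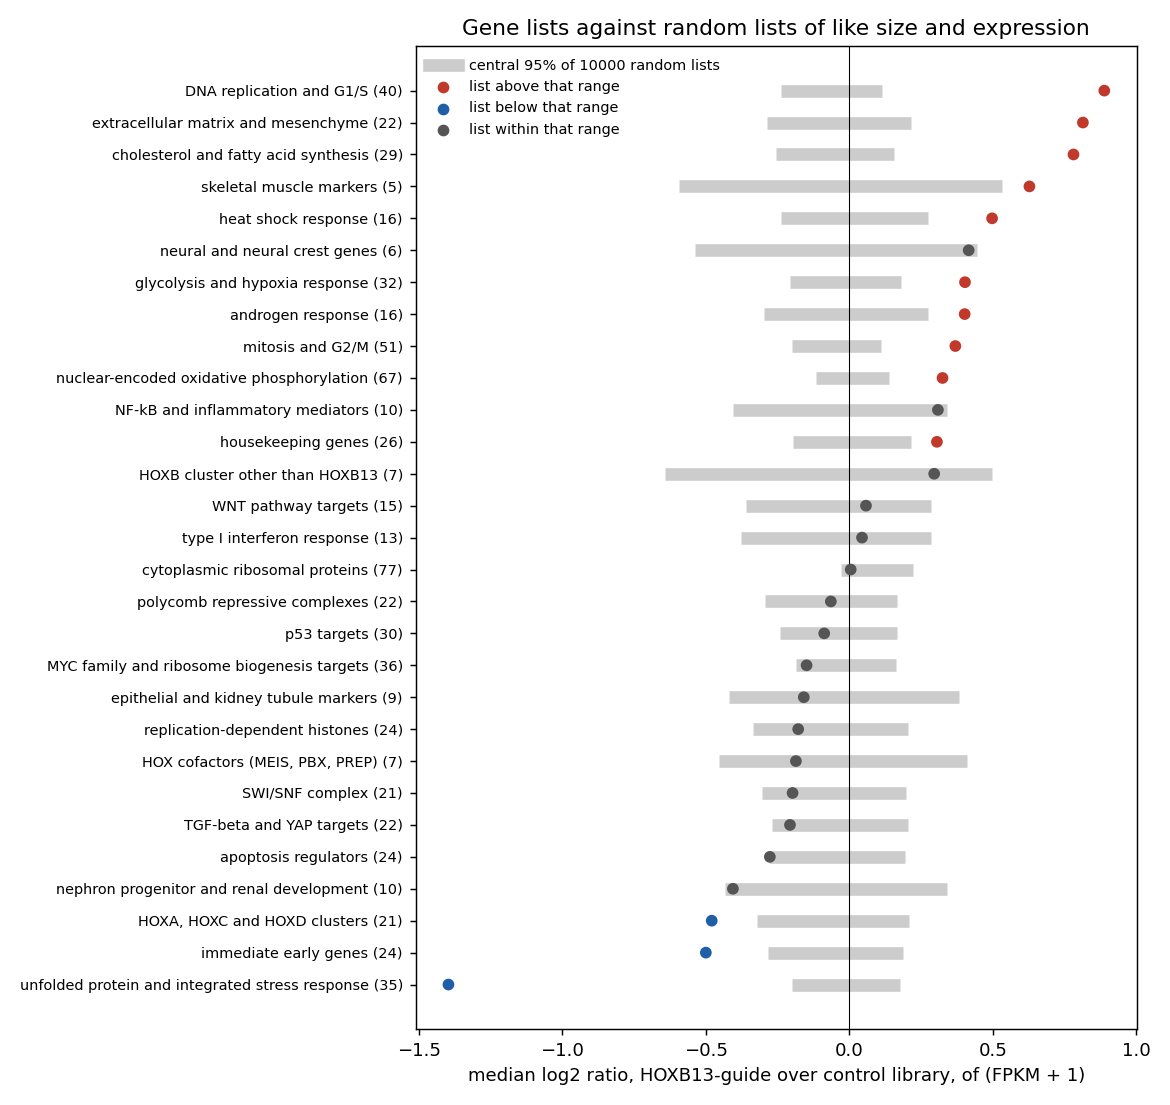
Median log2 ratio, HOXB13-guide over control library, of (FPKM + 1) for the 29 gene lists with at least 5 tested members (number tested in parentheses). Grey bars span the central 95% of 10000 random lists of the same size and expression; 10 medians lie above that range, from 0.31 for housekeeping genes to 0.89 for DNA replication, and 3 below it, the stress list at −1.40 being the lowest.

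Among signalling lists, immediate early genes were lower as a list, with 6 of 24 tested members at least 2-fold lower, 2 at least 2-fold higher and a median of −0.50 (percentile 0.01). JUN had 4.83 FPKM in the control and 1.46 in the HOXB13-guide library and ATF3 84.1 and 33.3, whereas the phosphatase gene DUSP5 had 1.11 and 6.38 and PHLDA1 0.177 and 2.04. In all 19 members had ratios below 0 and 5 above it. FOS, at 4.39 and 6.15 FPKM, and EGR1, at 3.41 and 4.06, both named outside the rule, were not lower. The median was −0.42 without ATF3, which the stress list also holds, and −0.09, within the random range, with no filter on low values. TGF-beta and YAP targets had 22 tested members, 1 higher and 4 lower past 2-fold, and a median of −0.21 within the range. TGFB1 had 33.3 and 12.8 FPKM, AJUBA 25.2 and 7.27, and ID4 39.3 and 15.1. WNT pathway targets had 15 tested members and a median of 0.06, with CCND1, the cyclin D gene, at 26.5 and 54.3 FPKM and NOTUM at 1.24 and 0.0211 as the members past 2-fold. Type I interferon genes had 13 tested members, a median of 0.04 and a mean of −0.06, with IFI6 at 10.7 and 28.0 FPKM and ISG20 at 7.79 and 1.92. The NF-kB and inflammatory list had 10 tested members and a median of 0.31 (percentile 96.4, within the range), with ICAM1 at 3.03 and 0.405 FPKM.

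The lists of p53 targets, apoptosis regulators, MYC and ribosome biogenesis targets and cytoplasmic ribosomal proteins lay within the random range. The p53 list had 30 tested members, 1 higher and 2 lower past 2-fold, and a median of −0.09. Its lower members were SESN2, at 122 FPKM in the control and 16.9 in the HOXB13-guide library, and GDF15, at 175 and 56.4, both also known to be induced through ATF4. SPATA18 was listed at 0 in the control and had 2.15 FPKM in the HOXB13-guide library. Apoptosis regulators had 24 tested members and a median of −0.28 (percentile 2.59), just inside the limit at percentile 2.5. The MYC list had 36 tested members, 2 higher and 2 lower past 2-fold, and a median of −0.15. MYC itself had 112 and 53.1 FPKM and MYCL1 12.6 and 4.22, while LDHA had 178 and 481. The 77 ribosomal proteins had a median of 0.00 and RPL7A, at 1005 and 2063 FPKM, as the only member past 2-fold.

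Markers of other cell types were mostly below the limit for testing in both libraries. Of the endothelial list 2 members were tested, EGFL7 at 19.2 FPKM in the control and 31.4 in the HOXB13-guide library and ENG at 6.96 and 6.03. Of the leukocyte list 3 were tested, CD68 at 102 and 111 FPKM, AIF1 at 29.5 and 34.4 and CSF1R at 3.25 and 0.348. Of the short structural RNAs 3 were tested, RMRP at 5.04 and 9.15 FPKM, RPPH1 at 1.19 and 0.912, and VTRNA1-1 at 18.2 and listed at 0. The mitochondrially encoded mRNAs had no tested member because none of their listed symbols had a value in the deposited tables. The same was true of most of the 20 listed short structural RNAs, so neither list was measured as low. In all, 10 of the 33 lists stood above their random range, 3 below it and 16 within it, and 4 had fewer than 5 tested members.

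**Figure D3:**
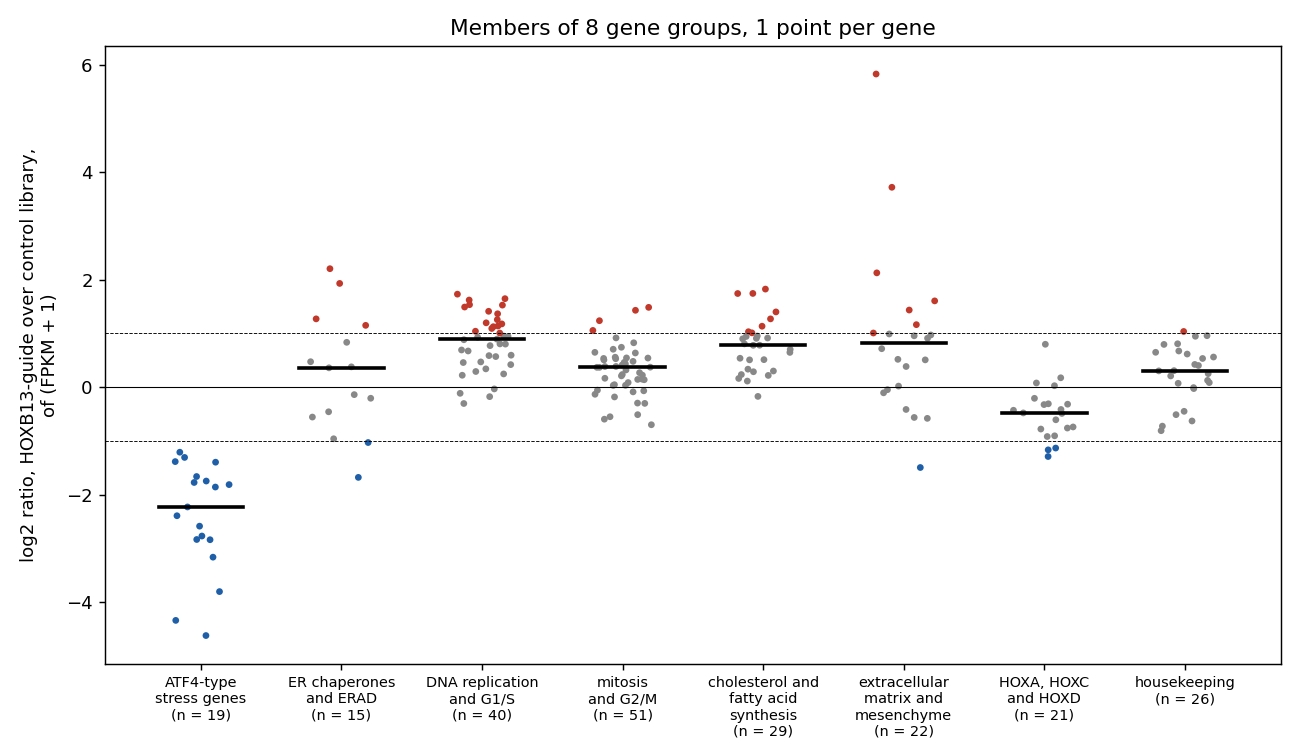
Log2 ratios, HOXB13-guide over control library, of (FPKM + 1) for the members of 8 gene groups, with 1 point per gene, black bars for medians, dashed lines at 2-fold, red for at least 2-fold higher and blue for at least 2-fold lower. The stress list without VEGFA (log2 −2.60), which was placed in neither group, is drawn as 19 ATF4-type genes, all at least 2-fold lower, and 15 endoplasmic reticulum chaperone and degradation genes with a median of 0.36, a division made after the data were seen. The housekeeping median is 0.31.

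Chromosome medians stayed close to the median of all genes. They ran from −0.12 on chromosome 18 to 0.09 on chromosome 7. Chromosomes 2, 6 and 19 lay below the random range of like gene sets, at −0.09, −0.10 and −0.11, and chromosomes 7, 11, 21 and 22 above it, at 0.09, 0.02, 0.08 and 0.03, so that 7 of 23 stood apart. On chromosome 17 the 466 tested genes centromeric of HOXB13 had a median of −0.05, within the range, and the 292 telomeric genes had a median of 0.05, above it (percentile 99.9).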

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

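Centring on the housekeeping list and the lists with members left out were chosen after the data were seen, and all other settings were planned. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The HOXB13 ratio lay between −1.81 and −1.04 under all alternatives. With a pseudocount of 0.1 FPKM 849 genes were at least 2-fold lower, and with a pseudocount of 5 FPKM 236 were higher and 221 lower, since the pseudocount widens or shrinks the ratios of low genes by construction. Centring on the housekeeping list, whose median of 0.31 was subtracted from every ratio, gave 287 higher and 1255 lower. The number of lists standing apart ran from 8 to 11 above and from 2 to 4 below the random range, and that of chromosomes from 6 to 9. Of 375 alternative values over 29 lists, 359 kept the call, 10 gained and 6 lost it, and none changed sign with a call. With no filter on low values the androgen, immediate early, matrix and muscle lists lost their calls, because genes near 0 in both libraries entered them. The glycolysis list lost its call by the mean, the apoptosis list gained one under 4 settings, the nephron progenitor list under 3, and the neural (pseudocount 5), NF-kB (no filter) and ribosomal protein (minimum of 5 FPKM) lists under 1 each, for which the cause was not tested. Of 1498 alternative values over 139 named genes, 1458 kept their side of 2-fold, 11 passed it and 29 fell short of it. The unit limits all low genes, since FPKM carries no counts and depth was estimated for the library and not for each gene.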

Other observations

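The gene groups of this part and the tests of each explanation were chosen after the results were seen, whereas the HOXB list, chromosome and HOXB13 values they draw on were planned. The 19 members of the stress list grouped as ATF4-type, which are ATF4 itself and genes taken as its targets or partners, were at least 2-fold lower in the HOXB13-guide library without exception. Their median log2 ratio was −2.23, with a range of −4.62 to −1.21. The cytoplasmic aminoacyl-tRNA synthetases, which charge transfer RNAs and include ATF4 targets, went the same way, with 7 of 20 at least 2-fold lower, none higher and a median of −0.82 (percentile 0 of random lists). WARS had 261 FPKM in the control and 45.5 in the HOXB13-guide library, and GARS had 384 and 99.7. The 17 mitochondrial synthetases had a median of −0.02, within the random range.

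Of 14 tested DLX and related homeobox genes 2 were at least 2-fold higher and 3 at least 2-fold lower, with a median of −0.35 (percentile 2.61, within the random range). SHOX2 had 74.0 FPKM in the control and 5.70 in the HOXB13-guide library, DLX1 48.5 and 3.48, and DLX2 48.7 and 6.01, whereas DLX5 had 0.102 and 2.02 and DLX6 0.0996 and 1.22. Of 6 tested semaphorin 3 and neuropilin genes 3 were at least 2-fold higher and none 2-fold lower, with SEMA3B at 0.34, SEMA3F at 0.10 and SEMA3D at −0.77 on the log2 scale among the others. The neuropilin receptors NRP1 and NRP2 had 0.333 and 0.426 FPKM in the control and 12.5 and 14.9 in the HOXB13-guide library, alongside their ligand SEMA3C at 0.00837 and 24.9. Of 9 tested S100 genes 4 were at least 2-fold higher, with a median of 0.84. The 12 tested tropomyosin and actin-binding genes had a median of 0.41, near the housekeeping median of 0.31, with TPM1 as the only member past 2-fold.

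As to the lower ATF4-type genes, a general difference in stress of the endoplasmic reticulum might lower its chaperones too, and their median was 0.36. They went both ways, with 7 of 15 below 0 and HERPUD1 (−1.68) and HYOU1 (−1.03) at least 2-fold lower. HSPA5 had 246 FPKM in the control and 179 in the HOXB13-guide library. Their lower quartile of −0.51 lay above the upper quartile of −1.71 of the ATF4-type genes, but the groups were divided after the values were seen. How far each group moves with such stress was not measured, so the comparison cannot decide. Scaling moves all genes about alike, and the median of all tested genes was −0.05, which argues against scaling as the source of an ATF4-type median of −2.23. The 4 other scalings left it at −2.17 or lower, but they moved all genes so little that they add no separate check. A nutrient or density difference between the 2 single cultures was set against the cytoplasmic synthetases, which were lower too (median −0.82, 5 of 20 above 0). They include ATF4 targets, so their lower level is part of the same pattern and gives no separate check. With 1 culture per guide, such a difference cannot be told apart from an effect of the guide. The biological explanation, that HOXB13 targeting lowers ATF4 output, remains an untested hypothesis.

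Some genes were near absent from 1 library and plainly expressed in the other: without short RNAs, 13 genes had under 0.1 FPKM in the control and at least 5 in the HOXB13-guide library, among them IGFBP3, PROM1, SDC2, SEMA3C, TRIM4 and RWDD2B, and KLHDC7B, NUDT11, PLD1 and STC2 had the opposite. Of 8704 genes at 5 FPKM or more in the control, 29 had less than 10% of that level in the HOXB13-guide library. Gain or loss of whole chromosomes is opposed by chromosome medians of at most 0.117 in size, and, of 8662 genes at 5 FPKM or more in the HOXB13-guide library, the 64 over 10-fold higher than in the control lay on 19 chromosomes. Admixed SMARCB1-intact cells as a source of the gained genes would raise SMARCB1, which had 0.113 FPKM in the control and 0.0577 in the HOXB13-guide library beside a median of 26.6 for the tested SWI/SNF members. Both SMARCB1 values lie near the floor and the level in intact cells was not measured, so no bound on such cells can be set and these values cannot decide. A clonal difference between the populations was not tested.

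For HOXB13 itself, loss of the whole HOXB cluster or of the chromosome arm beyond HOXB13 would lower its neighbours, but the telomeric genes had a median of 0.0529 and the other HOXB genes one of 0.30. That HOXB median was raised by HOXB6 and PRAC, which reached 1 FPKM in the HOXB13-guide library only. The lowest tested member, HOXB2, was at −0.39, against −1.50 for HOXB13. These values cannot address a loss confined to HOXB13 itself. Read counting error is excluded by the upper bound of 34.8% of the control level. The spread of genes of like level between these cultures stays open, since 2.5% of 200 such genes had a ratio as low, and without a second library per guide it cannot be told apart from loss of the mRNA through editing, a candidate explanation that was not tested.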
